A study of Rattus norvegicus with 8 samples.

How the data were processed

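RNA was extracted with a column kit and libraries were made with a strand-specific Agilent SureSelect kit, per the labels' protocols, and sequenced on an Illumina MiSeq, per the series design. The authors deposited 1 table with an FPKM value per gene and sample, per the file headers, for 4 control and 4 OGD samples. Per the submitters' processing notes, reads were handled with Trimmomatic and FastQC and the genome build was rn6 (Rnor_6.0). The aligner, the program that estimated FPKM, its annotation release and its use of strand are not given in the sources used here. FPKM divides fragments by gene length and by library total, so a large change in a few abundant genes moves all others, and it holds no counts. Samples were grouped by their treatment labels.

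Because the deposited values are FPKM, the test fixed for normalized values was used. Genes with at least 1 FPKM in at least 4 samples were kept (11149 of 32662). log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (trended empirical Bayes, model with group only), with Benjamini-Hochberg adjustment and a threshold of 0.05. The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. There were 25 lists with 594 entries, of which 575 matched a row by symbol, 12 of these by an older symbol, and 19 were unmatched. Among these was Gars1 of the ATF4 list, which the table holds as Gars. Older symbols came from a RefSeq gene table of another build (GRCr8), used for names only. 444 symbols stood on more than 1 row, of which list members took the row with the highest mean, and 53 rows had no symbol. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 24 lists that had tested members. The shares of 4 marker lists were compared by exact two-sided permutation, with Benjamini-Hochberg adjustment over the 4.

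Named genes were the 8 largest rises and 8 largest falls among genes with a symbol (not a clone or locus identifier) past the threshold, with a mean of at least 1 FPKM and every OGD sample beyond every control sample. To these came the 2 members with the smallest p of each list, and the 2 highest members of each marker list. Some genes selected this way are not reported here. The table gives no gene positions, so none are printed.

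Depth was read from genes of at most 0.5 FPKM, whose values in 2 samples stand in ratios of whole numbers times the worth of 1 fragment. Between 861 and 1057 genes were compared with control replicate 1, and 79.7% to 82.5% of ratios were whole within 0.01 on the log2 scale. This gives relative depth only, and no interval from counts could be made. Several genes used by most cells were listed at 0 in all samples (Hprt1, Ndufa1 and Rps6), so a value of 0 may be a failed estimate. Values of overlapping genes and of close copies are uncertain. No 2 samples held identical values.

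The procedure was tested on simulated data for the OGD comparison (11149 genes, 50 changed at each fold). It recovered 28%, 74%, 90% and 98% of genes changed 1.25, 1.5, 2 and 4-fold, with 9 false calls among 154. It made 0 calls with no change. The simulation changed far fewer genes than were called in the data, and only genes above a set control level. Its noise was normal and independent between genes, whereas real genes vary together. These rates are thus not those of the real comparison. The alternatives were quantile normalization, no filter, a filter of 5 FPKM, a pseudocount of 0.1, limma without trend, the replicate number as a block, each sample left out, a minimum fold change of 2, and for lists an estimated correlation and fry. Ranges of adjusted p given for lists include both of these. Unlike camera, fry asks whether list members change at all, not whether they change more than other genes. It gave the low end of the range for several lists. Chosen after seeing the data were rescaling outside mitochondrially encoded genes, median-centring, and leaving out control replicate 1 and OGD replicate 4 together. Alternatives that need counts were not run. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.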

Results

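Messenger RNA was measured by RNA sequencing in primary oligodendrocyte precursor cells of Sprague Dawley rats, the dividing glial cells that give rise to myelinating oligodendrocytes. The 8 samples fell into 2 groups of 4, a control group and a group kept for 6 h without oxygen and glucose (oxygen glucose deprivation, OGD), a culture model of ischaemia. A treatment time of 6 h was recorded for the control group too. Recorded alike for all samples were 4 to 5 days of culture, 20% serum, 2 mM glutamine, 10 ng/ml each of PDGF and FGF, 2% B27 and 1% antibiotic. Cells came from the cortex of pups aged 1 to 2 days and were taken from mixed glial cultures as the cells that did not adhere. Values were FPKM (fragments per gene, scaled by gene length and by the library's total) for 32662 genes, of which 15753 were listed at 0 in every sample. Total fragment numbers per sample are unknown, but the steps between low values gave relative depths from 0.816 (OGD replicate 2) to 1.18 (OGD replicate 4), with control replicate 1 set to 1. Between 14095 and 14444 genes had a value above 0 in a sample. Genes of at least 1 FPKM numbered 11157.5 ± 71.8 in control and 10955.8 ± 74.7 in OGD libraries (SD, n = 4 each; exact two-sided permutation p = 0.0286, not adjusted). Correlations of log2 values across the tested genes, which are not independent replicates, were 0.981 to 0.988 within the control group, 0.975 to 0.986 within the OGD group and 0.940 to 0.953 between groups.

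The comparison asked which transcripts differed after 6 h of OGD. By camera at a preset correlation between genes, the lists of the response to low oxygen, of glycolysis and of the amino acid stress response were higher in OGD. Those of DNA replication and ER protein folding were lower, as were those of precursor markers and myelin, each with about as many members falling as not. None of these calls held with an estimated correlation (adjusted p = 0.0878 to 0.623). Of 11149 tested genes, 5519 (49.5%) changed, 2527 upward and 2992 downward, and 467 of them by at least 2-fold (227 up, 240 down). The groups did not overlap for 44.7% of the tested genes (2304 with OGD above, 2684 with OGD below), where chance gives 2.86%. The tests were limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, so fold changes of low genes are understated.

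On the log2(FPKM + 1) scale, which ranks genes near 0 in control too low, the largest rise was that of Vegfa (ENSRNOG00000019598), the growth factor of blood vessels, from 7.36 ± 0.949 FPKM in control to 266 ± 59.6 FPKM in OGD (SD, n = 4 each). Its log2 change was 4.98 with a standard error of 0.15 (limma, adjusted p = 1.24e-08). Bhlhe40 (ENSRNOG00000007152), a transcriptional repressor induced by low oxygen, rose from 1.85 ± 0.291 to 42.2 ± 7.26 FPKM. Chac1 (ENSRNOG00000014387), a glutathione-degrading enzyme, rose from 2.04 ± 0.582 to 39.6 ± 5.11 FPKM, and Slc2a1 (ENSRNOG00000007284), a glucose transporter, from 5.42 ± 0.797 to 46.5 ± 4.98 FPKM. Ankrd37, Ak4, Adm and Ciart completed the 8 largest rises, with log2 changes of 3.88, 3.87, 3.56 and 3.46. Ak4, a mitochondrial adenylate kinase, was listed at 0 in control replicates 1 and 2, at 0.448 FPKM in control 3 and at 0.934 FPKM in control 4, and at 17.2, 22.6, 17.9 and 14.8 FPKM in OGD 1 to 4.

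On the same scale the largest fall was that of Txnip (ENSRNOG00000021201), a glucose-responsive inhibitor of glucose uptake, from 8.25 ± 0.549 to 0.280 ± 0.156 FPKM, a log2 change of -2.86 ± 0.12 (SE, limma adjusted p = 3.93e-08). Mgea5 (ENSRNOG00000017822), the enzyme that removes O-GlcNAc from proteins, fell from 22.1 ± 1.63 to 3.03 ± 0.117 FPKM. Lbh (ENSRNOG00000039902) fell from 184.5 ± 20.8 to 37.1 ± 8.50 FPKM, and Erbb3 (ENSRNOG00000004964), a receptor for neuregulin, from 18.3 ± 2.98 to 3.93 ± 0.465 FPKM. Nrarp, Fam212b, Mt2A and Klf10 completed the 8 largest falls, with log2 changes of -2.24, -2.19, -2.09 and -1.97.

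**Figure D1:**
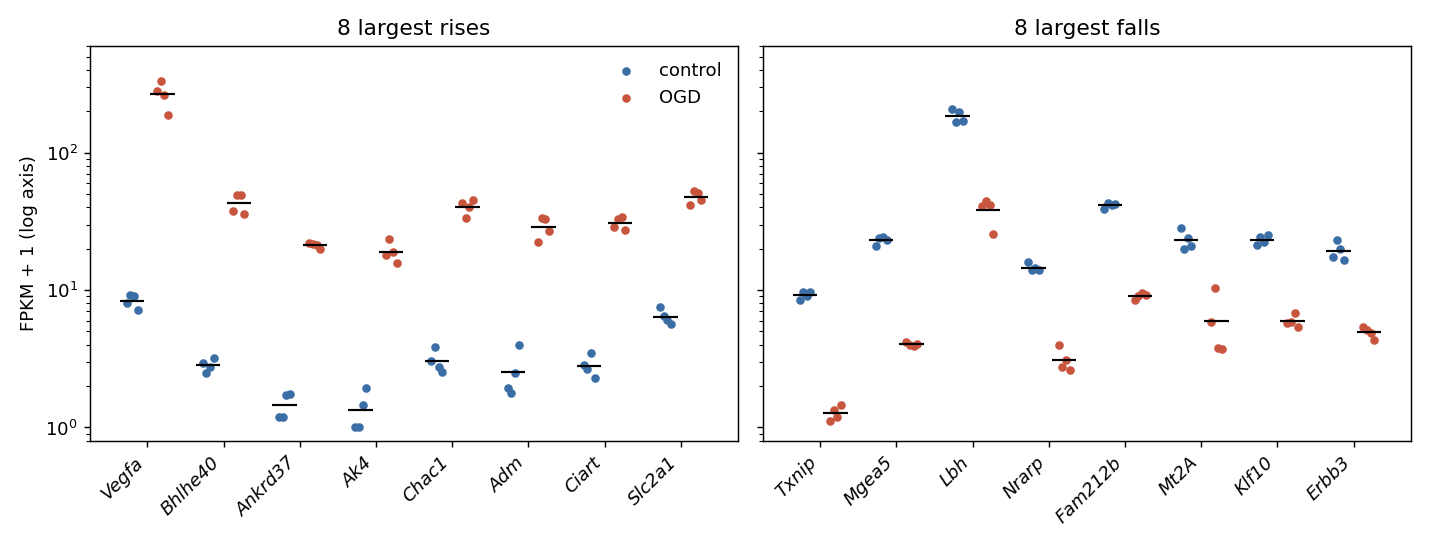
FPKM + 1 on a log axis for the 8 genes with the largest rises (left) and the 8 with the largest falls (right), 1 point per library (n = 4 per group) and a bar at each group mean. Every OGD library lies beyond every control library for these genes, as the rule that chose them required.

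Targets of the hypoxia-inducible factors rose together. Of 25 tested members, 22 rose, 0 fell and 3 did not pass the test, with the same 22 adjusted over the list alone, and the median member was 2.38-fold higher on the FPKM + 1 scale. The list was higher than other genes (camera, adjusted p = 2.00e-15, and adjusted p = 0.0878 with an estimated correlation between genes). Glycolytic genes and glucose and lactate transporters followed, with 13 of 17 members rising, 0 falling and 13 rising adjusted over the list alone. Their median log2 change was 0.48 (camera, adjusted p = 4.45e-08, and adjusted p = 0.271 with an estimated correlation). Ldha, the lactate dehydrogenase subunit of anaerobic glycolysis, rose from 68.4 ± 3.55 to 207.5 ± 13.2 FPKM.

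Genes of the ATF4 response, which acts when amino acids are short or protein synthesis is stressed, also rose. Of 25 tested members, 20 rose, 1 fell and 4 did not pass, and adjusted over the list alone 22 rose and 1 fell. The median log2 change was 0.98 (camera, adjusted p = 3.19e-13, and adjusted p = 0.0878 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose from 8.32 ± 0.669 to 39.9 ± 2.33 FPKM, and the falling member was Wars, the tryptophanyl-tRNA synthetase, at -0.64 on the log2 scale. Chaperones and quality control genes of the endoplasmic reticulum went the other way, with 16 of 22 falling, 3 rising and 3 not passing, both over all genes and adjusted over the list alone. The median log2 change was -0.35 (camera, adjusted p = 0.00568, and adjusted p = 0.271 with an estimated correlation). Hspa5, the main ER chaperone BiP, fell from 139.1 ± 7.50 to 67.1 ± 3.24 FPKM, while Herpud1, a component of ER-associated degradation, rose from 12.3 ± 1.29 to 54.1 ± 2.21 FPKM. The other 2 rising members were Pdia4 (0.29) and Crebrf (0.50). In the same OGD libraries the median log2 change of microglial markers was -1.12.

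The remaining stress lists had members on both sides and were not called by camera. In the heat shock list 2 of 12 rose and 5 fell (adjusted p = 0.385), with the same counts adjusted over the list alone; Dnaja1 fell by 0.50 and Chordc1 rose by 0.54 on the log2 scale. In the p53 and apoptosis list 4 of 19 rose and 6 fell (adjusted p = 0.800), again the same over the list alone, with Tp53inp1 at -1.36 and Aen at 0.78. In the NRF2 and oxidative stress list 1 of 18 rose and 8 fell (adjusted p = 0.0944; 1 and 8 adjusted over the list alone), with Mt2A at -2.09. In the autophagy and lysosome list 3 of 21 rose and 9 fell (adjusted p = 0.256; 3 and 9 adjusted over the list alone), with Becn1 at -0.38 and Neu1 at 0.87. Without OGD replicate 4 the NRF2 list was called (adjusted p = 0.0259, range over 19 alternatives 0.0166 to 0.623).

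**Figure D2:**
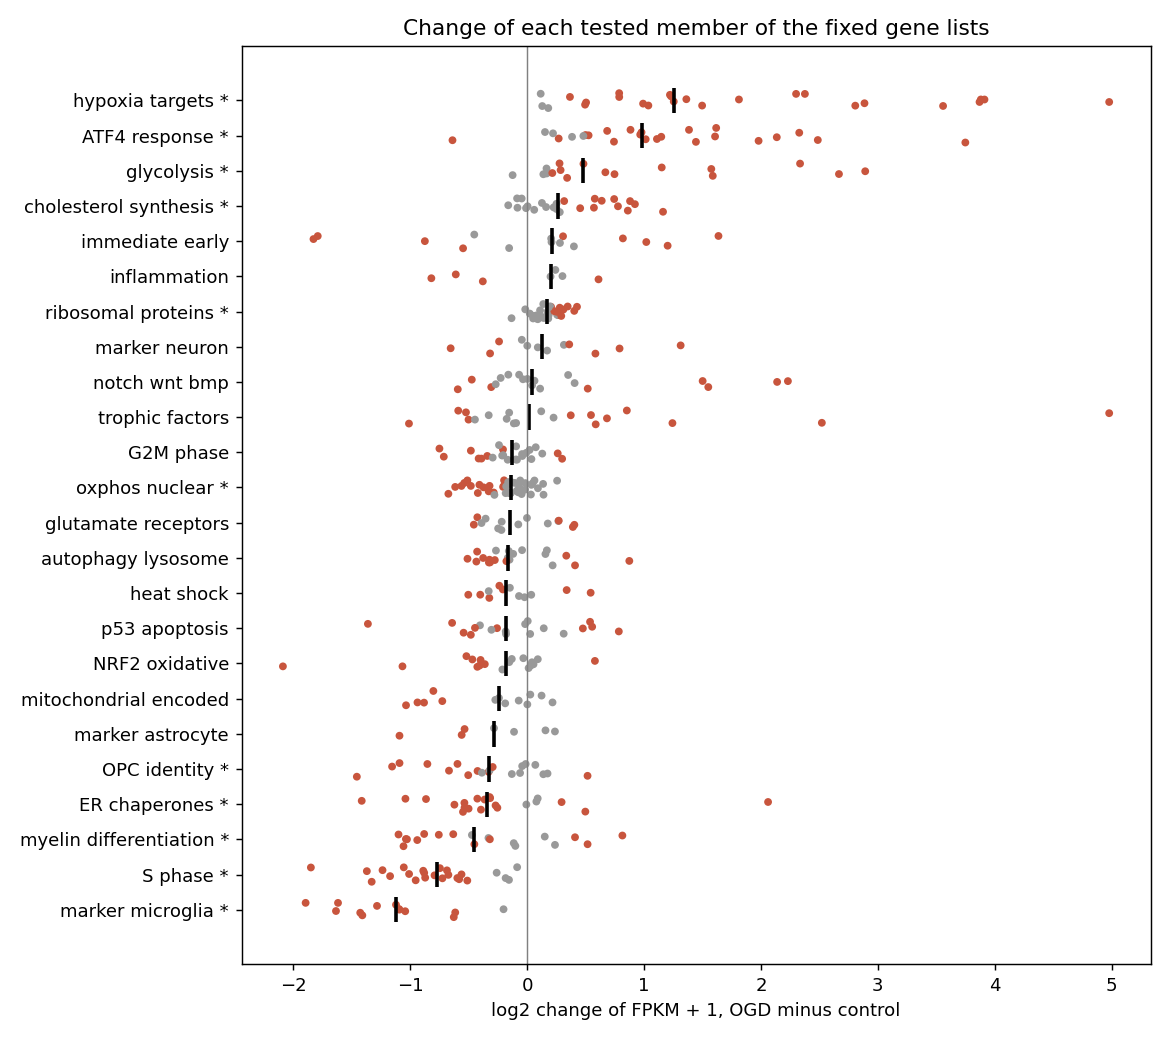
Log2 change (OGD minus control) of every tested member of 24 gene lists, 1 point per gene, with adjusted p under 0.05 in red and the others in grey, a black bar at each list median and an asterisk where camera called the list. The medians run from -1.12 for microglial markers to a 2.38-fold rise for hypoxia targets.

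Genes of S phase and DNA replication fell, and those of G2 and mitosis were mostly not past the test. Of 24 S phase members, 20 fell, 0 rose and 4 did not pass, with 21 falling adjusted over the list alone, and the median log2 change was -0.77 (camera, adjusted p = 4.70e-10, and adjusted p = 0.271 with an estimated correlation). Ccne1 and Ccne2, the E cyclins of S phase entry, fell from 15.1 ± 0.127 to 3.51 ± 0.652 FPKM and from 19.0 ± 1.43 to 6.71 ± 0.494 FPKM. Of 24 G2 and mitosis members, 7 fell and 2 rose (6 and 1 adjusted over the list alone), with a median of -0.13 (camera, adjusted p = 0.146). Ccna2, which also acts in S phase, fell by 0.75 and Cenpf by 0.71 on the log2 scale. Without OGD replicate 4 the G2 and mitosis list was called lower, with a median of -0.22 (adjusted p = 0.0124, range over 19 alternatives 0.00533 to 0.771), and its median was -0.08 without OGD replicate 1 or OGD replicate 2 and -0.07 with quantile normalization. The S phase mean minus the mitosis mean per library was -1.08 in control and -1.71 in OGD (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows; n = 4 each), a test chosen after the lists had been seen. The microglial markers fell in these libraries too, with a median log2 change of -1.12.

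Markers of the precursor state were lower in part. Of 20 tested members, 10 fell, 1 rose and 9 did not pass, the same adjusted over the list alone, with a median log2 change of -0.33 (camera, adjusted p = 0.0196, and adjusted p = 0.623 with an estimated correlation). Olig1, a transcription factor of the lineage, fell from 794.5 ± 41.4 to 356.5 ± 28.0 FPKM and C1ql1 from 119.9 ± 16.8 to 42.9 ± 5.50 FPKM, and the rising member was Sox8 (0.52). Of 19 myelin and differentiation genes, 10 fell, 3 rose (Tcf7l2, Tspan2 and Mog) and 6 did not pass, with 11 falling and 3 rising adjusted over the list alone. Their median was -0.45 (camera, adjusted p = 0.0372, and adjusted p = 0.623 with an estimated correlation). Cnp fell from 358.9 ± 29.8 to 194.0 ± 8.21 FPKM. The call on precursor markers was lost with quantile normalization (adjusted p = 0.0927) and without OGD replicate 4 (adjusted p = 0.0532, range over 19 alternatives 0.00570 to 0.623), and that on myelin genes without control replicate 1 (0.0737), OGD replicate 3 (0.0619) or OGD replicate 4 (0.0507; range 0.00427 to 0.623). The falling members of both lists fell in libraries in which the median log2 change of microglial markers was -1.12.

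Of 19 Notch, Wnt and BMP pathway genes, 5 rose and 3 fell, the same adjusted over the list alone (camera, adjusted p = 0.234). Id2 and Id1, inhibitors of basic helix-loop-helix factors, rose from 84.5 ± 7.81 to 240.6 ± 18.6 FPKM and from 5.87 ± 1.72 to 30.6 ± 3.59 FPKM. Of 24 cholesterol synthesis and uptake genes, 11 rose and 0 fell, the same adjusted over the list alone, with a median of 0.26 (camera, adjusted p = 9.21e-05, and adjusted p = 0.585 with an estimated correlation). Insig1 rose from 36.4 ± 1.39 to 63.0 ± 2.68 FPKM.

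Nuclear genes of the respiratory chain shifted slightly downward. Of 42 tested members, 15 fell, 0 rose and 27 did not pass (12 fell adjusted over the list alone), with a median of -0.14 (camera, adjusted p = 0.0142, and adjusted p = 0.727 with an estimated correlation). Cycs fell by 0.62 and Atp5g1 by 0.67 on the log2 scale, in libraries in which the microglial median was -1.12. Quantile normalization ended the call, with a median of -0.06 (adjusted p = 0.123), as did leaving out control replicate 1 (0.0935; range over 19 alternatives 0.00153 to 0.727). Of the 13 protein-coding genes of the mitochondrial genome, 5 fell, 0 rose and 8 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.146, and 0.0361 without OGD replicate 2; range 0.0361 to 0.771). The 5 were Mt-nd1, Mt-nd4, Mt-nd4l, Mt-nd5 and Mt-nd6, while Mt-nd2 (-0.24) and Mt-nd3 (-0.19) did not pass. Mt-nd6 fell from 2813 ± 222.4 to 1401 ± 346.6 FPKM, and values of Mt-nd4 and Mt-nd4l are uncertain because these genes overlap. The value of Mt-nd6 is uncertain too, since the use of strand in estimating FPKM is not given. Its control level was far above that of Mt-nd4 (58.2 FPKM). These 13 genes held 25.1% to 27.9% of summed FPKM in control libraries and 29.6%, 30.4%, 23.4% and 20.4% in OGD replicates 1 to 4. Of 32 ribosomal protein genes, 10 rose and 0 fell (3 adjusted over the list alone), with a median of 0.17 (camera, adjusted p = 0.00442, and adjusted p = 0.709 with an estimated correlation). Without OGD replicate 4 the median was 0.11. Rps3 rose by 0.43 and Rpl32 by 0.35 on the log2 scale; such genes have many pseudogene copies, which makes their values uncertain.

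Of 20 trophic factor genes, 8 rose and 4 fell, the same adjusted over the list alone (camera, adjusted p = 0.234). Their median was 0.01, and on either side of 0 when single libraries were left out (-0.03 without OGD replicate 3, 0.08 without control replicate 1) or median-centred (-0.02); with a filter of 5 FPKM the list was called higher, with a median of 0.55 (adjusted p = 0.0189, range over 19 alternatives 0.00204 to 0.623). Vegfa was among the rising members. Of 7 inflammation genes above the filter, 1 rose and 3 fell (2 and 3 adjusted over the list alone). Their median was 0.20 and their mean -0.07 (camera, adjusted p = 0.997). That median was 0.12 without control replicate 2 and 0.30 with a filter of 5 FPKM. Irf1 and Csf1 fell by 0.82 and 0.61, in libraries in which 12 of 13 microglial markers fell (median -1.12). Of 15 immediate early genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera, adjusted p = 0.494), with a median of 0.21 against a downward direction in the fry test. Dusp6 and Egr1, which follow MAP kinase activity, fell by 1.83 and 1.79 on the log2 scale. Of 14 glutamate receptor and transporter genes, 3 rose and 2 fell (3 and 1 adjusted over the list alone). Their median was -0.15 against an upward camera direction (camera, adjusted p = 0.928). That median was -0.05 without OGD replicate 4, -0.04 with a filter of 5 FPKM and -0.10 with quantile normalization. Slc1a1 rose by 0.39 and Grik2 by 0.40.

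Markers of other cell types were read in the same libraries. Of 13 microglial markers, 12 fell, 0 rose and 1 (Trem2) did not pass, with the same 12 adjusted over the list alone, and the median log2 change was -1.12 (camera, adjusted p = 3.98e-05, and adjusted p = 0.585 with an estimated correlation). C1qa and C1qc, subunits of complement C1q, fell from 60.0 ± 14.8 to 19.3 ± 7.02 FPKM and from 55.0 ± 13.4 to 17.3 ± 5.51 FPKM. The microglial list held 0.0574% ± 0.0146 of summed FPKM in control and 0.0220% ± 0.00705 in OGD (SD, n = 4 each; exact two-sided permutation p = 0.0286, adjusted p = 0.0571 over 4 lists), and every OGD library lay below every control library. This p is the smallest that 4 against 4 allows, and over 4 lists it passes adjustment only where at least 3 lists reach it, so the share did not pass. Neuronal markers held 0.0276% ± 0.000814 and 0.0375% ± 0.00278 (exact permutation p = 0.0286, adjusted p = 0.0571), with 4 of 12 genes rising and 3 falling, the same adjusted over the list alone (camera, adjusted p = 0.254). Tubb3 rose by 0.79 and Syn1 fell by 0.32 on the log2 scale. Astrocyte markers held 0.0254% ± 0.000767 and 0.0250% ± 0.00212 (exact permutation p = 0.771), with 3 of 7 genes falling and 0 rising (4 and 1 adjusted over the list alone; camera, adjusted p = 0.256). Their mean log2(FPKM + 1) was 3.15 to 3.30 in control and 2.72 to 3.04 in OGD libraries (exact permutation p = 0.0286, adjusted p = 0.0457 over 24 lists, a test chosen after the data were seen). This permutation p passes adjustment only because 15 of the 24 lists reach it. The fry test gave an adjusted p of 0.0140 (range over 19 alternatives 0.0140 to 0.623). Sparcl1 was at 57.3 ± 4.42 and 52.8 ± 2.05 FPKM and Sox9 at 37.1 ± 2.94 and 44.1 ± 5.96 FPKM, neither past the test (limma, adjusted p = 0.197 and 0.0639). Without OGD replicate 1 Sox9 passed (adjusted p = 0.0182, range over 17 alternatives 0.0182 to 0.226). None of the 12 matched vascular and stromal markers reached the filter: Kdr was at 0.110 ± 0.0600 and 0.0992 ± 0.0483 FPKM, Cdh5 was listed at 0 in OGD replicates 2 and 4 and at 0.0801 and 0.0525 FPKM in OGD 1 and 3, and the list's share was 8.57e-05% and 4.68e-05% (exact permutation p = 0.114, adjusted p = 0.152).

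**Figure D3:**
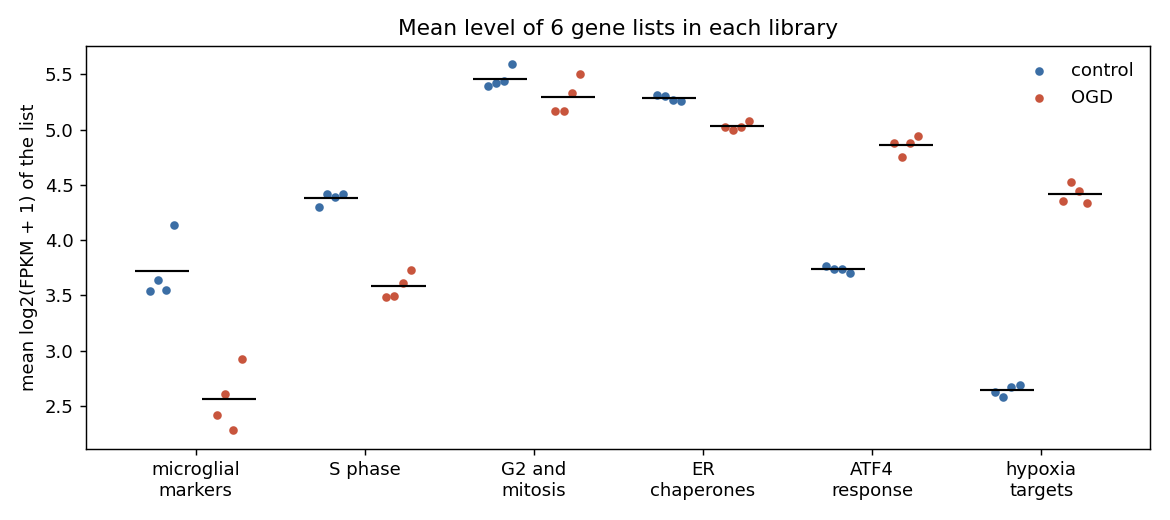
Mean log2(FPKM + 1) over the tested members of 6 gene lists in each library, 1 point per library (n = 4 per group) with a bar at the group mean. The groups are apart for 5 of the lists and overlap for G2 and mitosis, where OGD replicate 4 lies highest of its group.

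In all, camera called 5 lists higher and 6 lower at the preset correlation of 0.01, and none of these calls held with an estimated correlation. Nothing in the labels says that samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Members named because a list held 5 or fewer of their kind were chosen after their values were seen.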

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

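In 5 of 136 groups of 4 libraries, 1 library stood far from the other 3, where chance gives about 6.8. Tp53inp1 was at 13.3 FPKM in control replicate 4, against 15.0 to 15.4 FPKM in the other controls. Neu1 was at 18.8 FPKM in control replicate 1, against 12.4 to 12.9 FPKM. Ccne1 was at 15.0 FPKM in control replicate 2, against 15.2 FPKM in the others, a small distance within a tight group. C1qa, a microglial gene, was at 81.9 FPKM in control replicate 4, against 49.4 to 55.0 FPKM. The vascular and stromal share of summed FPKM was 0.000130% in control replicate 3, against 6.77e-05% to 7.33e-05%.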

How the results depend on the processing

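Chosen only after the data were seen were rescaling outside mitochondrially encoded genes (5347 changed genes), median-centring (5488), and leaving out control replicate 1 and OGD replicate 4 together (5379). Over the alternatives that kept the threshold, 4460 (filter of 5 FPKM) to 5535 (no filter) genes changed, against 5519. Leaving out each library gave 4830 to 5494 genes (2197 to 2484 up, 2608 to 3010 down), 5 lists called higher and 4 to 7 called lower. A minimum fold change of 2 left 467 genes (227 up, 240 down), by its construction. With a correlation estimated from the data, which allows for genes that vary together, camera called 0 lists higher and 0 lower at the adjusted threshold. It called 3 lists at an unadjusted p under 0.05, while fry called 15. Among changed genes 45.8% rose, and 40.9% to 50.2% under other scalings. Of 984 values of named genes, 980 kept their call, and the others were those of Sox9. Of list values 423 kept their call, 21 lost it, 12 gained it and 0 reversed. Leaving out each library, the microglial share differed by -0.0393 to -0.0285 percentage points, the neuronal by 0.00901 to 0.0108, the astrocyte by -0.00129 to 0.000408 and the vascular by -4.78e-05 to -2.41e-05. Replicate numbers showed no clear pairing of the samples, and the labels do not say whether same-numbered samples share a culture. Deviations of same-numbered samples, across genes, correlated at -0.22, 0.16, 0.01 and 0.09, and control replicate 4 alone correlated best with its own number. With the replicate number as a block 5509 genes changed, 5250 of them among those reported. Alternatives that need counts were not run, since the deposited table holds none. Absolute depth is unknown, so the counting error of genes near 1 FPKM is unknown too.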

Other observations

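The gene groups of these opening paragraphs, the tests of scaling, of S phase against mitosis, of list means per library, of splits by their make-up and of single libraries, and the further versions of the microglial spread were chosen only after the results were seen. Of 20 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 13 rose and 2 fell, with a median log2 change of 0.62 (camera, adjusted p = 1.07e-05 over 7 added lists, and adjusted p = 0.148 with an estimated correlation). Cars rose from 14.3 ± 1.14 to 60.6 ± 5.54 FPKM and Iars from 8.91 ± 0.531 to 36.2 ± 2.69 FPKM (SD, n = 4 each), while Dars and Wars fell by 0.62 and 0.64. Of 18 circadian clock genes, 14 rose and 1 fell, with a median of 0.67 (adjusted p = 5.91e-06, and adjusted p = 0.148 with an estimated correlation). Nfil3 rose by 1.92 and Nr1d1 by 1.39, and Per1 was the falling member; Bhlhe40 and Rora are also hypoxia list members, and Nars, Wars and Aars also ATF4 list members, as is Gars, which rose by 0.65 but was not matched in that list. Of 34 splicing factors, 18 fell and 6 rose, with a median of -0.22 (adjusted p = 0.00772, and adjusted p = 0.148 with an estimated correlation). Sfpq fell from 190.9 ± 4.52 to 75.3 ± 8.46 FPKM, in libraries in which 12 of 13 microglial markers fell (median -1.12).

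Feedback genes of ERBB and MAP kinase signalling (4 of 19 rose, 9 fell, adjusted p = 0.103) and genes of lipid synthesis for myelin (5 of 17 rose, 4 fell, adjusted p = 0.303) were not called; the median of the lipid genes was 0.02, and -0.01 when median-centred. A pair of entries that the table names only after the mitochondrial genome rose, ENSRNOG00000043866 from 372.8 ± 15.9 to 1593 ± 396.6 FPKM (limma, adjusted p = 2.73e-06) and ENSRNOG00000030478 from 466.3 ± 47.0 to 1292 ± 333.7 FPKM (adjusted p = 5.35e-05), while 5 named genes of that genome fell. The table does not say which transcripts they are.

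Of the 35 splits of the 8 samples into 4 and 4, 1, the real one, gave as many as 5519 changed genes. The others gave at most 2. This is the smallest share that 35 splits can give, and the other splits mix the groups, which widens the spread on each side. An arbitrary division of these samples is thus argued against for that count. A chance difference between cultures is not, since samples of a group may not be separate cultures. For the number of lists called at the preset correlation chance cannot be excluded, since 7 of the 35 splits, the real one included, gave at least its 11 lists, and the highest other gave 13. Of the 6 others, 5 set 3 libraries of 1 group with 1 of the other and so keep part of the group difference; of the 18 splits with 2 libraries of each group, 1 gave as many. By list means per library, 15 of 24 lists did not overlap between groups, among them 9 of the 11 called lists (exact permutation p = 0.0286, adjusted p = 0.0457). The called lists that overlapped were the nuclear respiratory chain and ribosomal proteins. This p is the smallest that 4 against 4 allows, and it passes adjustment only because many lists reach it. Lists that camera did not call are among the 15, and 44.7% of single tested genes did not overlap either. The separation of list means is thus no separate support for the calls.

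Microglial markers were lower in OGD. The median change of all tested genes was at lowest -0.0686 under 4 scalings, but scaling itself keeps that value near 0. The microglial median was -1.09 to -1.15 under the same scalings. A shift shared by all genes is thus argued against, while a change in total RNA cannot be seen in FPKM. A second list of microglial genes had a median of -0.68, with 95.5% of 22 members below 0, which is consistent with a lower share of microglia, or of their RNA, in the OGD libraries. Whether that share is the whole cause stays open. The changes spread more among 35 microglial genes than in any other split (1 of 35 as large, SD 0.421 against at most 0.306). Adding 1 to FPKM shrinks the falls of low genes, which adds to this spread and understates the second list's fall. Without the added 1, over 16 of these genes with a control mean of at least 5 FPKM, the SD was 0.468 against at most 0.348. But the labels name no sort beyond collecting cells that did not adhere, and markers of several cell types were measured. Some of the microglial genes may thus be made by other cells too, and unequal falls then follow from a lower share as well. The bound set before the test would have excluded a share alone, in all 8 versions run, but it had not allowed for such genes; a response of microglia to OGD also stays open.

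S phase genes were lower in OGD, and mitosis genes less so. The S phase median (-0.77 as reported) was -0.74 to -0.80 under 4 scalings, while that of all tested genes was at lowest -0.0686, a value that scaling keeps near 0. A shift shared by all genes is thus argued against as the source of the S phase fall, while a change in total RNA cannot be seen in FPKM. Fewer cycling cells of all phases, as the whole cause, are argued against by the unequal change of the lists (exact permutation p = 0.0286 for their difference), as far as both lists are equally tied to cycling cells. A second list of replication genes had a median of -0.32, with 15 of 29 falling and 1 rising; this lies past the bound of -0.3 set before, but the median was -0.29, short of it, when rescaled outside mitochondrial genes. It is consistent, weakly, with lower expression of S phase and replication genes in general; an arrest before S phase was not tested.

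ER chaperones fell while ATF4 response genes rose. The ER median stayed at -0.31 or lower under 4 scalings, but each of these keeps the median of all tested genes near 0. The outcome was thus nearly fixed, and a scaling difference is not excluded for the ER fall by itself. A change in total RNA cannot be seen in FPKM. A shift shared by all genes leaves the gap between the ER and ATF4 lists as it is. An effect of 1 library alone is argued against, since the ER median stayed at -0.34 or lower whichever library was left out. A test of whether the lower microglial share carries the ER fall had been planned as a correlation within each group, and no coefficient is given because 4 libraries per group are too few. The list means did not go one way: control replicate 4 was highest for microglial markers (4.14) and lowest for ER chaperones (5.26), while OGD replicate 4 was highest for both (2.93 and 5.08). What the test was to show in both groups was thus not met, nor was its opposite, and that explanation stays open, as does an effect of OGD on the transcripts themselves.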
